A study of Homo sapiens with 51 samples.

How the data were processed

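A2780, an established human ovarian carcinoma cell line, was profiled on 51 Affymetrix HG-U95Av2 arrays with biotin-labelled cRNA made from polyA RNA. Per the labels, cells were exposed for 2 h to cisplatin, to oxaliplatin or to drug-free medium and then grew without drug. The time course used doses that inhibited growth by 90 percent over 72 h (IC90: cisplatin 25 µM, oxaliplatin 32 µM), with harvests before treatment and 0, 2, 6, 16 and 24 h after it. The concentration series was harvested at 16 h, with cisplatin and oxaliplatin at 2.6 and 2.8 µM for IC10, 4.0 and 4.8 µM for IC25, 6.4 and 8.5 µM for IC50, 12 and 17 µM for IC75, and the time-course doses for IC90.

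The deposited values are RMA signals, 1 per probe set and array; the authors carried out background correction, normalization between arrays and summary over probes. The unit is intensity on a linear scale: the deposited numbers ran from 5.18 to 18069, with array medians from 140 to 155, and log2 was taken here. The RMA implementation, its version, and whether all 51 arrays were normalized together are not given in the sources used here. Of 12625 probe sets, 67 were Affymetrix controls and stayed out of every gene test. Of the other 12558, 10943 matched 1 gene, 545 matched several and 1070 matched none; the last 2 classes were tested apart. For the 1928 genes with several probe sets, the one with the highest mean over all arrays was used, which left 8226 genes. No filter on low values was applied. Arrays give no read depth, and the number of arrays limits the precision.

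The labels made 25 groups. Each gene was fitted with limma 3.58.1 (R 4.3.3) as 1 mean per group over all 51 arrays with eBayes, and contrasts were adjusted by the Benjamini-Hochberg method over the 8226 genes within each contrast, two-sided, with a threshold of 0.05. Adjusted p and "called" refer to this limma test for genes; the adjusted p of a gene list is that of camera. Groups with 1 array were assumed to vary like the replicated groups. No 24 h control array exists among the samples, so the 24 h arrays were compared with the 16 h controls. Dose slopes were fitted by limma on the 29 arrays taken at 16 h against nominal percent growth inhibition, 1 slope per drug with a shared control intercept, and are given as the log2 change over 90 percent. A ± after a log2 change is its standard error. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the plots.

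Gene lists, comparisons, a first set of alternative settings and the rule for named genes were written before the data were examined. The rule allowed, per IC90 contrast, dose slope and drug difference, the 10 largest rises and falls among called genes whose arrays all lay on the same side; the 4 members with the smallest p of each list and contrast; and 20 fixed genes. Of the fixed genes, 18 were measured and 2 (BTG2 and RRM2B) were not. The 27 lists covered p53 targets, G1/S genes, G2/M genes, replication-dependent histones, nucleotide excision repair, Fanconi and homologous recombination, mismatch repair, immediate early genes, short-lived transcripts, the integrated stress response, the unfolded protein response, heat shock, NRF2 targets, metallothioneins, ribosomal proteins, ribosome biogenesis, cholesterol synthesis, the interferon response, NF-kappaB targets, apoptosis, platinum transport and detoxification, hypoxia and glycolysis, housekeeping genes, and markers of fibroblasts, leukocytes, endothelial cells and epithelial cells. Lists were matched by exact current symbol; this replaced, after the data were seen, a match that also used synonyms and had drawn paralogs into 3 lists. They were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated per list. The preset is liberal here: it called 8 lists between the 16 h controls and the arrays taken before treatment, of which 1 held with an estimated correlation, and 2 between the groups taken before cisplatin and before oxaliplatin, of which 0 held.

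The numbers in the labels were checked as pairs by correlating the deviations of equally numbered arrays from their group means. For cisplatin against oxaliplatin at IC90 and 16 h, the 4 correlations were 0.436, 0.549, 0.537 and 0.37, and for oxaliplatin against control 0.406, 0.144, 0.217 and 0.149; a block on the number left both counts within 1.5 times their value. For cisplatin against control, 1 of the 4 was -0.272, so the numbers were not read as pairs. At IC10 the correlation between the drugs was -0.453; the block called 13 genes there, crossed pairing 6 and the fit without a block 0.

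The labels name no hybridization runs. After the data were seen, 3 runs were inferred: the time course, the cisplatin series and the oxaliplatin series. The deviations of the 16 h control and IC90 arrays from their group means were cut into 2 clusters. By these clusters, 2 of the 5 cisplatin and 2 of the 4 oxaliplatin IC90 arrays at 16 h belonged to the time course. Deviations cancel within a group, so such a cut tends to divide each group and to place both drugs in each cluster. All arrays at other times were placed in the time course by label. Every other treated 16 h array was placed in the series of its drug. The 2 series were thus set apart by drug label, not by clusters in the data. Of the 4 controls at 16 h, 1 resembled the time course, 2 the cisplatin series and 1 the oxaliplatin series (correlation with the nearest array 0.785, 0.689, 0.691 and 0.798). For the controls and IC90 arrays the assignment used expression itself. A control assigned by its resemblance to IC10 arrays can absorb part of a low-dose effect. Results are given pooled, with the inferred run as a block, and within runs.

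Alternatives covered all probe sets, brighter genes only, eBayes with trend and robust, array weights, quantile normalization, median centring, the replicate block, each replicate left out, only the 2 groups compared, other untreated arrays as control, a log2 dose scale, camera with an estimated correlation, and controls split between the drugs. Added after the data were seen were the inferred run block, within-run values, the GAPDH 3' minus 5' difference as a covariate, leaving out the 2 arrays that stood apart (oxaliplatin 0 h number 1 and 2 h number 2), slopes on treated arrays only, and crossed pairing at IC10. The model was tested on simulated data with 50 genes changed at each of 4 sizes: for cisplatin at IC90 and 16 h it recovered 68 percent of 1.5-fold and 96 percent of 2-fold changes, with 12 false among 194 calls. It recovered 12 and 62 percent for cisplatin at 2 h, 22 and 70 percent at 24 h, 42 and 88 percent at IC50, and 54 and 88 percent between the drugs at IC90 and 20 and 82 percent at IC75, both at 16 h. The simulated noise was independent between genes and arrays, with no runs and no outlying arrays. The rates therefore test the model and need not hold for the real arrays.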

Results

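The data set holds 51 arrays of A2780 ovarian carcinoma cells in 25 groups. Before treatment there were 5 arrays, 2 from dishes labelled for cisplatin, 2 for oxaliplatin and 1 control. At IC90, each drug had 2 arrays at 0 h, at 2 h and at 6 h and 1 array at 24 h; at 16 h there were 5 cisplatin and 4 oxaliplatin arrays. Drug-free controls had 1 array at 0 h, 2 h and 6 h and 4 at 16 h. IC10, IC25, IC50 and IC75 had 2 arrays per drug, all at 16 h. Array medians lay between 140 and 155 intensity units. The labels do not say whether replicate arrays came from separate cultures, so p-values measure only the spread between these arrays. Untreated cells were compared as a background: 0 of 8226 genes were called by limma between the 16 h controls and the arrays taken before treatment (477 at unadjusted p under 0.05; 3 without control number 1), and 0 between the groups taken before each drug (45 at unadjusted p under 0.05). Untreated arrays were not alike in every comparison. Between the 16 h controls assigned to the cisplatin series (2 arrays) and the oxaliplatin series (1 array), the ribosomal protein median differed by 0.172 and the interferon median by -0.325. For genes named as called at IC90 and 16 h, each array of the first group lay on the same side of the mean of the second.

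The comparison of cisplatin at IC90 with control at 16 h asked which transcripts differed after a highly inhibitory exposure. Targets of the transcription factor p53 rose together: 16 of the 20 measured members were higher and 0 lower, over all genes and also adjusted over the list alone, with a list median of 1.43 on the log2 scale (camera adjusted p = 9.7e-31, 0.000166 with an estimated correlation). GDF15, a stress-secreted cytokine, rose from 8.57 ± 0.17 (SD, n = 4) to 12.59 ± 0.24 (SD, n = 5), a log2 change of 4.02 ± 0.26 (adjusted p = 7.35e-13). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 3.37 ± 0.25, the kinase gene PLK2 by 3.49 ± 0.36 and TP53I3, which encodes an oxidoreductase, by 3.04 ± 0.17. The death receptor gene TNFRSF10B rose by 1.19 ± 0.12 and MDM2, which encodes the ubiquitin ligase of p53, by 0.71 ± 0.13. The death receptor gene FAS stood at 0.09 ± 0.13 in its brightest probe set (0.32 ± 0.13 after oxaliplatin, neither called) and a further probe set was not called. In 4 other probe sets FAS was called higher, by 2.01, 1.84, 1.78 and 1.59 after cisplatin and 2.06, 1.91, 1.69 and 1.51 after oxaliplatin. Outside the list, the cell adhesion gene CEACAM1 rose by 3.15 ± 0.27, FEZ1 by 3.01 ± 0.17 and the lysosomal membrane gene LAMP3 by 2.47 ± 0.19.

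Mitotic genes were lower after cisplatin in part. Of 28 G2/M genes, 5 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.286; the list's call (adjusted p = 0.00144) was lost, with adjusted p = 0.657 with an estimated correlation. The mitotic kinase gene PLK1 fell by 1.07 ± 0.14, and KIFC1, which encodes a spindle motor, changed by -1.21 ± 0.25. MKI67, a proliferation marker, and CDC20, an activator of the anaphase-promoting complex, changed by -0.76 ± 0.16 and -0.74 ± 0.15. The 24 G1/S genes did not move as a list (1 higher and 2 lower, 1 and 3 adjusted over the list alone, median -0.008, adjusted p = 0.951). CCNE2, which encodes cyclin E2, was at 0.47 ± 0.32 (adjusted p = 0.313).

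Several smaller groups were called after cisplatin only at the preset correlation. Of 19 nucleotide excision repair genes, 5 rose and 0 fell, also adjusted over the list alone (median 0.215, adjusted p = 0.216 with an estimated correlation), among them the damage recognition genes DDB2 at 1.81 ± 0.22 and XPC at 1.37 ± 0.13, both of which are also in the p53 list, and RPA1, which encodes a subunit of the single-strand binding protein, at 0.67 ± 0.13. Of 25 immediate early genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.297 with an estimated correlation). CCN2, JUNB and NR4A1 rose by 2.16 ± 0.36, 1.11 ± 0.18 and 1.03 ± 0.17, and MYC fell by 0.61 ± 0.16. FOS stood at -0.06 ± 0.18 in its brightest probe set, but 2 other probe sets of FOS were called higher, at 1.78 and 1.06 after cisplatin and 2.20 and 1.72 after oxaliplatin. Of 25 short-lived transcripts, 6 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), with TOB1 at 1.64 ± 0.24 and HES1 at 1.40 ± 0.19. The 46 ribosomal protein genes had a median of 0.148 with 0 called by limma (adjusted p = 0.657 with an estimated correlation). The untreated controls of the inferred cisplatin and oxaliplatin series differed by 0.172 in this list.

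In all, limma called 810 of 8226 genes for cisplatin at IC90 and 16 h, 588 higher and 222 lower, of which 137 changed at least 2-fold; the median over all genes was -0.06. The count was sensitive to single arrays: it was 1353 without control number 1, 520 without control number 3, 539 without cisplatin number 2 and 517 without number 5. Array weights gave 3026 and leaving out 2 arrays of other groups that stood apart gave 1224. Within the inferred runs, 104 genes were called in the time course (2 against 1 array) and 299 in the cisplatin series (3 against 2), and the p53 target median was 1.06 and 1.46.

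Oxaliplatin carries a diaminocyclohexane ligand and an oxalate leaving group in place of the ammine and chloride ligands of cisplatin. At IC90 and 16 h it raised p53 targets too: 16 of 20 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median of 1.51 (adjusted p = 0.000162 with an estimated correlation). GDF15 rose by 4.30 ± 0.27 to 12.87 ± 0.53 (SD, n = 4), CDKN1A by 3.56 ± 0.26, TP53I3 by 3.39 ± 0.18 and PLK2 by 3.15 ± 0.38. FEZ1 rose by 3.59 ± 0.18, CEACAM1 by 3.43 ± 0.29 and RRAD, which encodes a small GTPase, by 3.75 ± 0.25. SAT1, the rate-limiting enzyme of polyamine breakdown, rose by 2.92 ± 0.28.

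Genes of the cell cycle fell together after oxaliplatin. Of 24 G1/S genes 18 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.821 (adjusted p = 8.65e-19, 0.000803 with an estimated correlation). CCNE2 fell by 2.38 ± 0.34, from 7.78 ± 0.75 (SD, n = 4) to 5.40 ± 0.54 (SD, n = 4). The replication licensing genes MCM6, MCM3 and MCM2 changed by -1.68 ± 0.14, -1.45 ± 0.15 and -1.23 ± 0.13, CDC6 by -1.39 ± 0.17, and FEN1, the flap endonuclease of lagging-strand synthesis, by -1.03 ± 0.13. Of 28 G2/M genes 24 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of -1.07 (adjusted p = 0.00648 with an estimated correlation). CCNA2, PLK1 and AURKB changed by -1.86 ± 0.20, -1.38 ± 0.14 and -1.25 ± 0.16. Of 14 Fanconi and homologous recombination genes, 6 fell and 1, RAD51C at 1.10 ± 0.20, rose (7 and 1 adjusted over the list alone; adjusted p = 0.166 with an estimated correlation).

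Of 25 immediate early genes 11 rose and 0 fell after oxaliplatin (13 and 0 adjusted over the list alone; adjusted p = 0.0415 with an estimated correlation), with CCN2 at 2.83 ± 0.38, CCN1 at 1.60 ± 0.23 and ATF3 at 1.55 ± 0.36. Of 25 short-lived transcripts 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.0415 with an estimated correlation). Within the inferred time course and oxaliplatin series the medians were 0.461 and 0.677 for immediate early genes and 0.326 and 0.447 for short-lived transcripts. With an estimated correlation both lists were called in the series and neither in the time course. Further lists were called only at the preset correlation, each with its adjusted p with an estimated correlation. They were apoptosis (6 higher, 1 lower of 31, adjusted p = 0.0595), platinum transport and detoxification (4 and 0 of 15, adjusted p = 0.0595, but 0.0487 within the oxaliplatin series and 0.364 within the time course), nucleotide excision repair (3 and 0 of 19, adjusted p = 0.195), the interferon response (5 and 0 of 24, adjusted p = 0.374), epithelial markers (3 and 0 of 9, adjusted p = 0.338), cholesterol synthesis (1 and 5 of 16, adjusted p = 0.338) and ribosomal proteins (0 and 0 of 46, adjusted p = 0.697). Adjusted over the list alone their counts were 6 and 1, 5 and 0, 3 and 0, 5 and 0, 3 and 0, 1 and 5, and 0 and 0. TAP1, a peptide transporter of antigen presentation, rose by 2.32 ± 0.16 and KRT18, a keratin of simple epithelia, by 2.04 ± 0.28.

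Limma called 1062 genes for oxaliplatin at IC90 and 16 h, 686 higher and 376 lower, of which 232 changed at least 2-fold. No single array moved this count by over 1.5 times, while array weights gave 2334 and a fit of only the 2 groups gave 668. Within the inferred runs it was 195 in the time course (2 against 1) and 415 in the oxaliplatin series (2 against 1); the G1/S median was -0.922 and -0.92, and the p53 target median 1.085 and 1.66.

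The same genes answered both drugs to a large extent. At IC90 and 16 h, 415 genes were higher after both and 87 lower after both, against 49 and 10.1 under independence, and 0 were called in opposite directions. The 4 controls were shared, which alone links the lists; with the controls split between the drugs, 183 to 237 genes were higher in both and 13 to 28 lower in both. Across genes, which are not independent replicates, the log2 changes correlated at 0.734. The correlation averaged 0.528 in simulations of unchanged groups with the same controls, and was 0.303 to 0.771 with the controls split between the drugs. The simulated arrays had independent noise. In the real data the deviations of equally numbered cisplatin and oxaliplatin IC90 arrays correlated at 0.37 to 0.549. Such shared variation can raise the real overlap and correlation, also with the controls split.

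The test of cisplatin against oxaliplatin at IC90 and 16 h asked where the compounds differed at equal growth inhibition; the micromolar doses differ (25 and 32). Cell-cycle genes were higher after cisplatin than after oxaliplatin. For G1/S genes, 17 of 24 were higher after cisplatin and 0 lower (20 and 0 adjusted over the list alone), with a median difference of 0.845 (adjusted p = 1.69e-33, 1.85e-05 with an estimated correlation). For G2/M genes the numbers were 18 and 0 of 28 (27 and 0 adjusted over the list alone, median 0.708) and for Fanconi and homologous recombination genes 9 and 0 of 14, also adjusted over the list alone (median 0.542), both with adjusted p = 0.00471 with an estimated correlation. CCNE2 differed by 2.84 (95% interval 2.18 to 3.50), FEN1 by 1.29 (1.04 to 1.55) and MCM6 by 1.10 (0.83 to 1.38). PRIM1, a subunit of DNA primase, differed by 1.38 ± 0.15, SPC25, a kinetochore gene, by 1.55 ± 0.22 and AURKB by 0.91 ± 0.15.

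**Figure D1:**
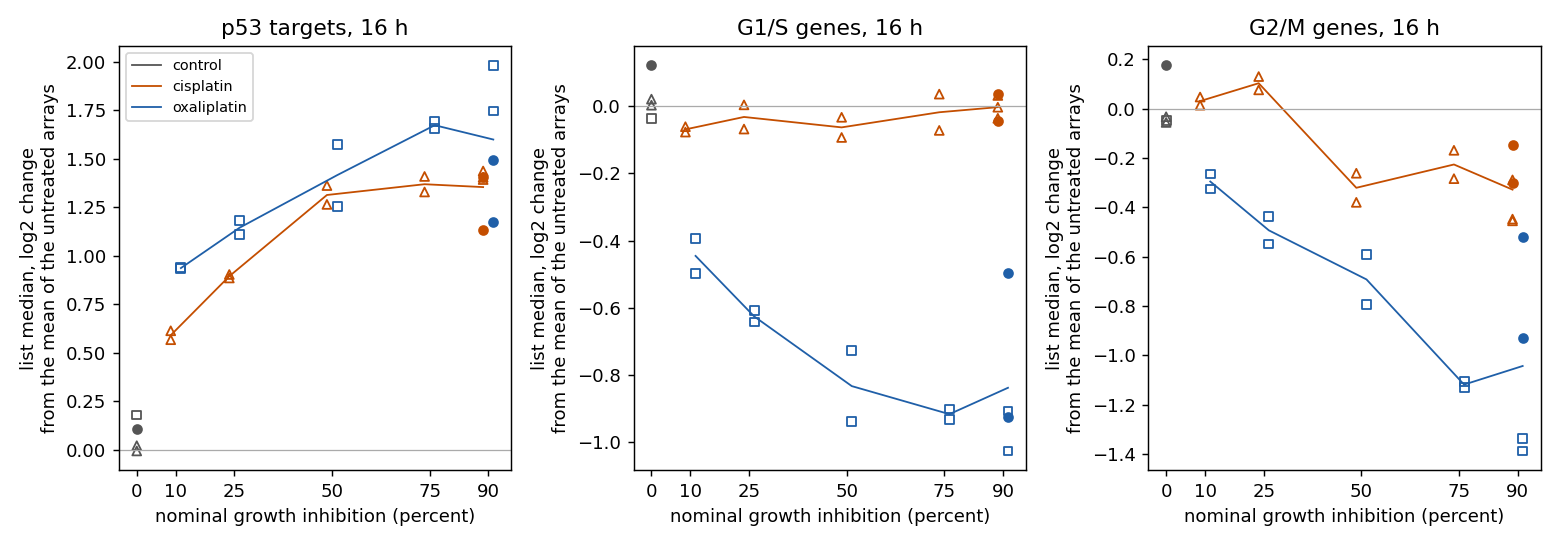
Median log2 change of the p53 target, G1/S and G2/M lists per array at 16 h against nominal growth inhibition in percent; lines join group means, filled circles are arrays of the inferred time course, open triangles and squares those of the inferred cisplatin and oxaliplatin series. After oxaliplatin at IC90 the G1/S medians of the 4 arrays lie between -1.026 and -0.495, below all 5 cisplatin arrays, which lie between -0.044 and 0.037.

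Other genes were higher after oxaliplatin. The histone genes H2BC5 and H2BC21 differed by -1.15 ± 0.19 and -0.98 ± 0.18, RRAD by -1.19 (95% interval -1.68 to -0.70), and CNN1, which encodes calponin, by -1.02 ± 0.18. KRT18 differed by -1.37 (-1.92 to -0.82), HMOX1, which encodes heme oxygenase, by -1.19 (-1.62 to -0.76), TAP1 by -0.67 (-0.97 to -0.37) and PSMB9, an immunoproteasome subunit, by -1.05 ± 0.19. With the inferred run as a block these last calls were lost, at -0.80 for KRT18 (adjusted p = 0.2), -0.81 for HMOX1 (0.069), -0.31 for TAP1 (0.6) and -0.46 for PSMB9 (0.267), while H2BC5, H2BC21, RRAD and CNN1 stayed narrowly past the threshold. Without oxaliplatin number 4, TAP1 was at adjusted p = 0.0629. At list level, epithelial markers, histones, the interferon response, immediate early genes, NF-kappaB targets and leukocyte markers were lower after cisplatin, and mismatch repair and the integrated stress response higher, only at the preset correlation (adjusted p = 0.0547, 0.233, 0.233, 0.245, 0.245, 0.5, 0.245 and 0.245 with an estimated correlation). The untreated controls assigned to the 2 series runs stood apart by -0.325 in the interferon list (camera adjusted p = 7.69e-05, 0.129 with an estimated correlation) and by -0.348 in epithelial markers, which was not called (0.0758, 0.712 with an estimated correlation), against -0.268 and -0.467 between the drugs in those runs (0.0466 for both with an estimated correlation). In the time course the drug differences of these 2 lists were -0.121 and -0.202 (0.238 for both with an estimated correlation).

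The p53 targets gave no call between the drugs as a list (median -0.161, adjusted p = 0.198); 0 were higher and 1 lower (1 and 2 adjusted over the list alone). The interval of the difference was -0.81 to 0.24 for GDF15, -0.69 to 0.32 for CDKN1A, -0.37 to 0.15 for MDM2, -0.41 to 0.11 for XPC and -0.22 to 0.70 for DDB2, which leaves room for differences of that size. The member called was TP53I11, at -0.68 ± 0.13.

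Limma called 305 genes between the drugs, 207 higher and 98 lower after cisplatin. The count was 113 without oxaliplatin number 3, 148 without oxaliplatin number 4 and 177 without cisplatin number 5, 749 with array weights, and 90 with the inferred run as a block. Within the time course (2 against 2) it was 22, with a G1/S median of 0.705 (camera adjusted p = 4.85e-25, 0.000315 with an estimated correlation), and between the series runs, where drug and run coincide, it was 569, with a G1/S median of 0.919. CCNE2 differed by 2.36 ± 0.42 (adjusted p = 0.013) in the time course and by 3.31 ± 0.38 between the series runs.

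The time course asked when changes began. At 0 h limma called 0 genes for cisplatin (71 at unadjusted p under 0.05). For oxaliplatin it called 5: FABP6, S100A7, HIPK2 and PDC were higher, by 1.05 ± 0.21, 0.97 ± 0.20, 0.83 ± 0.17 and 0.76 ± 0.15, and RNF115 was lower, by -0.96 ± 0.19, each at adjusted p = 0.0437. Without oxaliplatin number 1 this count was 0 and without number 2 it was 3551. Between the drugs at 0 h 1612 genes were called, 586 higher and 1026 lower after cisplatin, and 0 without oxaliplatin number 1, 0 without cisplatin number 2, 2973 without cisplatin number 1 and 3980 without oxaliplatin number 2. Oxaliplatin number 1 at 0 h had a high background signal. At 2 h, oxaliplatin number 2 had a GAPDH 3' minus 5' difference of 3.463, against 0.416 in number 1. The highest value elsewhere was 1.984, in cisplatin number 2 at 6 h. Counts at 2 h without oxaliplatin number 1 rest on oxaliplatin number 2. At 2 h PHF14 was called after cisplatin, at -1.41 ± 0.19 (adjusted p = 0.000359; 2 genes were called without cisplatin number 1), and limma called 0 genes after oxaliplatin (396 at unadjusted p under 0.05; 150 without number 1) and 0 between the drugs (634; 271 without oxaliplatin number 1 and 6 without cisplatin number 1).

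At 0 h camera called 3 lists for cisplatin, 5 for oxaliplatin and 14 between the drugs at the preset correlation, and at 2 h 1, 0 and 0. With an estimated correlation 0 of these held. Relative to all untreated arrays, G2/M medians at 2 h were -0.249 and -0.491 after cisplatin and -0.06 and -0.111 after oxaliplatin, against 0.056 in the control. At 6 h the p53 targets were higher as a list after both drugs, with no member called over all genes. After cisplatin the median was 0.335 (adjusted p = 1.02e-09, adjusted p = 0.0624 with an estimated correlation) and after oxaliplatin 0.547 (adjusted p = 7.68e-15, 0.018 with an estimated correlation), with 2 and 5 members higher adjusted over the list alone. GDF15 stood at 1.98 ± 0.47 (adjusted p = 0.333) and 2.37 ± 0.47 (adjusted p = 0.0775), CDKN1A at 1.62 ± 0.45 (adjusted p = 0.614) and 1.85 ± 0.45 (adjusted p = 0.237). G2/M medians were -0.52 and -0.539 (adjusted p = 0.0624 and 0.0774 with an estimated correlation), with 0 members called either way. The G1/S median was 0.263 after cisplatin (adjusted p = 0.308 with an estimated correlation). The gene called in both was NONO, an RNA-binding protein gene, at 1.97 ± 0.26 and 1.99 ± 0.26; the lone 6 h control had 9.71 against 10.69 to 11.63 in the other controls, so this rests on that array. Between the drugs at 6 h limma called 0 genes (254 at unadjusted p under 0.05; 1 without oxaliplatin number 2).

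All early comparisons with control rest on 1 control array. At 6 h this control had a p53 target median of 0.289 relative to all untreated arrays, the highest among them. The other untreated arrays lay between -0.305 and 0.18. On the same scale the 6 h arrays stood at 0.698 and 0.436 after cisplatin and 0.859 and 0.784 after oxaliplatin. With all untreated arrays pooled as the control, 10 genes were called at 2 h and 40 at 6 h for cisplatin, and 2508 at 0 h, 54 at 2 h and 56 at 6 h for oxaliplatin.

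**Figure D2:**
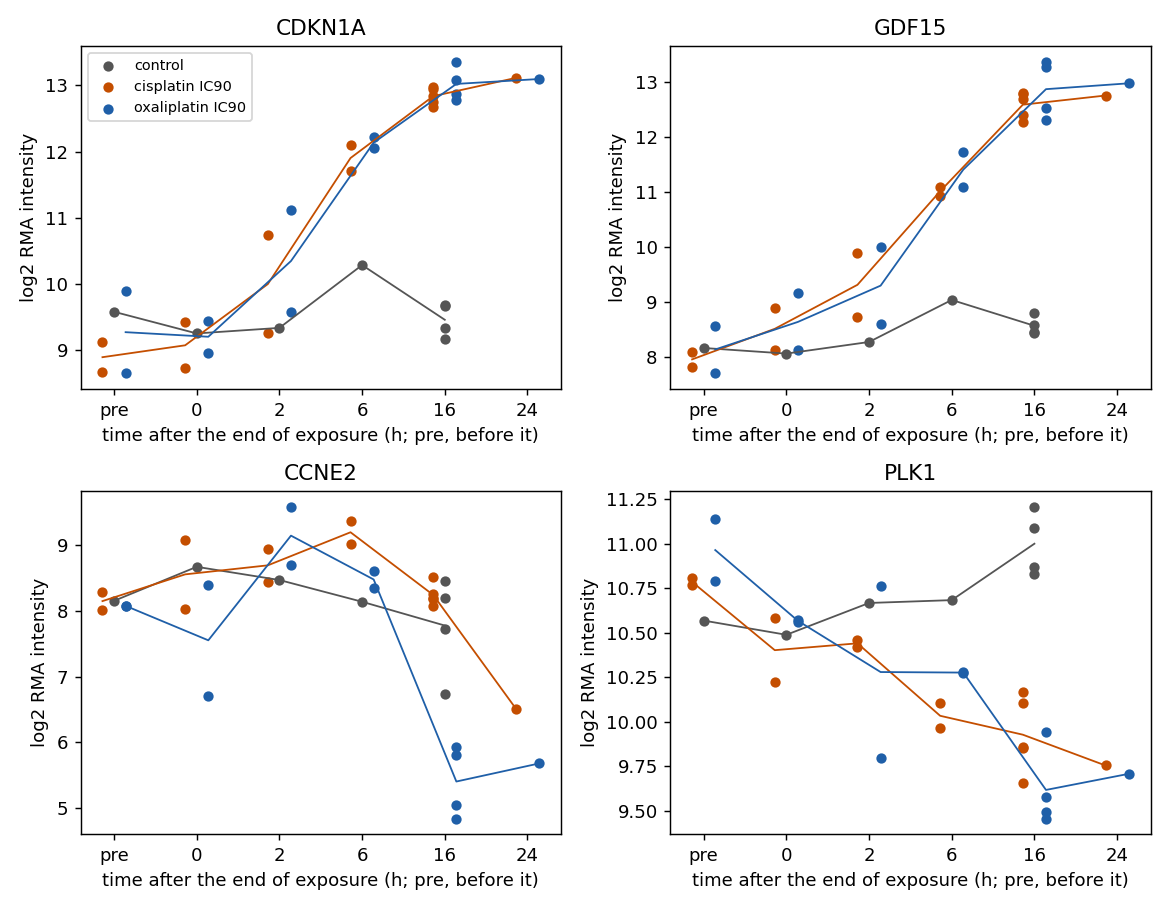
Log2 RMA intensity of CDKN1A, GDF15, CCNE2 and PLK1 per array against time after the end of exposure (hours, not to scale), with lines through group means, for control, cisplatin IC90 and oxaliplatin IC90; the 16 h points include arrays of the concentration series. CDKN1A at 16 h lies between 12.68 and 13.36 in the treated arrays and between 9.17 and 9.68 in the controls.

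At 24 h each drug had 1 array, compared with the 4 controls taken at 16 h, so time and treatment were not separated. GDF15 stood 4.19 ± 0.43 higher after cisplatin and 4.41 ± 0.43 after oxaliplatin, and CDKN1A 3.65 ± 0.41 and 3.63 ± 0.41. Of the p53 targets 11 and 14 of 20 were higher and 0 lower (16 and 15 adjusted over the list alone; adjusted p = 0.000139 and 0.000214 with an estimated correlation). G1/S genes, which had not moved as a list at 16 h after cisplatin, had a median of -0.514 at 24 h, with 2 lower and 0 higher (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.0875 with an estimated correlation). After oxaliplatin the median was -1.09 with 14 lower and 0 higher (16 and 0 adjusted over the list alone; adjusted p = 0.000409 with an estimated correlation). MCM6 differed from control by -1.52 ± 0.22 after cisplatin and -1.58 ± 0.22 after oxaliplatin, and SLC7A5, an amino acid transporter, by -2.04 ± 0.36 (adjusted p = 0.000544) and -1.11 ± 0.36 (adjusted p = 0.0714). Limma called 204 genes for cisplatin (133 higher, 71 lower; 330 with the GAPDH covariate, 349 without the 2 arrays that stood apart and 1262 with array weights) and 376 for oxaliplatin (257 higher, 119 lower; 1488 with array weights). Between the drugs it called 0 (259 at unadjusted p under 0.05); the G1/S median differed by 0.569, a value from 1 array of each drug that is not separated from variation between arrays.

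The concentration series asked how the 16 h response depended on dose. The p53 targets were already higher at IC10: 4 of 20 after cisplatin and 7 after oxaliplatin (12 and 14 adjusted over the list alone), with medians of 0.551 and 0.956 (adjusted p = 5.44e-05 and 0.000365 with an estimated correlation). Their medians were 1.02, 1.25 and 1.45 after cisplatin at IC25, IC50 and IC75, with 8, 13 and 13 members higher (14, 17 and 16 adjusted over the list alone), and 1.22, 1.43 and 1.62 after oxaliplatin, with 13, 15 and 17 higher (15, 18 and 19 adjusted over the list alone). Against the controls of their own inferred runs, the medians from IC10 to IC75 were 0.738, 1.08, 1.29 and 1.42 after cisplatin, with 3, 7, 12 and 13 members higher, and 0.891, 1.12, 1.42 and 1.56 after oxaliplatin, with 4, 6, 11 and 13 higher. GDF15 rose by 1.81 ± 0.33, 2.54 ± 0.33, 3.38 ± 0.33 and 3.75 ± 0.33 from IC10 to IC75 of cisplatin, and by 2.61 ± 0.33, 3.30 ± 0.33, 3.98 ± 0.33 and 4.52 ± 0.33 from IC10 to IC75 of oxaliplatin.

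G1/S genes fell with oxaliplatin from the lowest dose: medians were -0.448, -0.659, -0.8 and -0.906 from IC10 to IC75, with 1, 10, 11 and 14 of 24 members lower (11, 14, 19 and 19 adjusted over the list alone; adjusted p = 0.0124, 0.00152, 0.000609 and 0.000736 with an estimated correlation). After cisplatin the medians were -0.08, 0.017, -0.016 and 0.059 with 0 members called at any of the 4 doses, over all genes or over the list alone. CCNE2 changed by -1.38 ± 0.42 (adjusted p = 0.202), -1.65 ± 0.42 (adjusted p = 0.0255), -2.55 ± 0.42 and -2.91 ± 0.42 after oxaliplatin. Against the control assigned to the oxaliplatin series, in which CCNE2 was lower than in the other controls, it was -0.35 ± 0.51, -0.61 ± 0.51, -1.52 ± 0.51 and -1.87 ± 0.51, with only the last past the threshold (adjusted p = 0.0381). Within that run the G1/S medians were -0.342, -0.597, -0.807 and -0.868, with 0, 1, 8 and 11 members lower.

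Genes called rose with dose from 4 through 17 and 45 to 121 for cisplatin (IC10 to IC75) and from 23 through 187 and 383 to 671 for oxaliplatin, with more higher than lower at each dose. With the inferred run as a block the oxaliplatin counts were 8, 31, 152 and 297, and with the replicate number as a block 620, 882, 847 and 1242. The replicate numbers were not read as pairs, so the latter counts carry little weight. With array weights the counts did not rise steadily with dose. They fell from IC25 to IC75 for cisplatin and dropped at IC50 for oxaliplatin. At 2 arrays per dose these counts were fragile: without control number 4 the oxaliplatin counts at IC10 and IC25 were 149 and 443, and without oxaliplatin number 2 at IC25 and IC50 they were 35 and 137. For cisplatin, 0 genes were called at IC10 without either array, 5 at IC25 without either, 18 and 25 at IC50 without number 1 and number 2, and 41 and 68 at IC75. For oxaliplatin, 7 and 8 were called at IC10 without number 1 and number 2, 46 at IC25 without number 1, 696 at IC50 without number 1, and 266 and 336 at IC75. Without control number 2 the oxaliplatin count at IC25 was 107 and the cisplatin count 11; without control number 3 the cisplatin counts at IC10 and IC25 were 2 and 11.

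Between the drugs at matched inhibition, limma called 0 genes at IC10 (1120 at unadjusted p under 0.05), 45 at IC25, 34 at IC50 and 108 at IC75. The G1/S median difference was 0.399, 0.654, 0.708 and 0.94 (adjusted p = 0.194, 0.0101, 3.79e-05 and 0.000106 with an estimated correlation), with 0, 4, 7 and 11 members higher after cisplatin and 0 lower (9, 15, 18 and 15 higher adjusted over the list alone). At IC75 CCNE2 differed by 3.04 ± 0.48, FEN1 by 1.47 ± 0.19 and HMOX1 by -1.79 ± 0.32. Below IC90 the arrays were placed in runs by drug, so each inferred run holds 1 drug there. Drug and run are linked only through the controls and the IC90 arrays. With the run as a block the counts were 0, 0 and 1 at IC25, IC50 and IC75, but this block can absorb a drug difference. Without any 1 of the 4 treated arrays at most 1 gene was called at IC25. At IC75 the counts were 5 and 17 without cisplatin number 1 and 2 and 16 and 15 without oxaliplatin number 1 and 2. At IC50 they were 5 or 10 without cisplatin number 2 or 1 and 10 without oxaliplatin number 2.

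**Figure D3:**
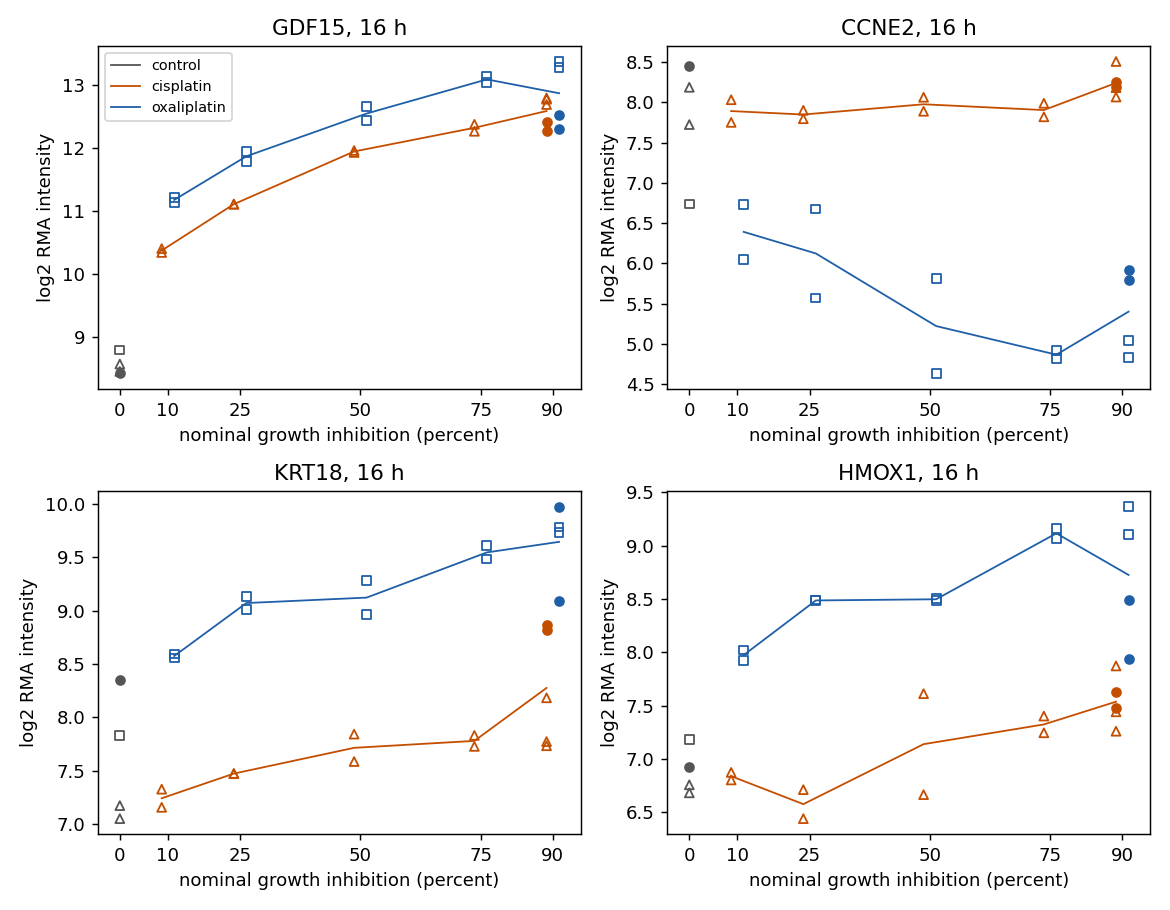
Log2 RMA intensity of GDF15, CCNE2, KRT18 and HMOX1 per array at 16 h against nominal growth inhibition in percent; lines join group means, filled circles are arrays of the inferred time course, open triangles and squares those of the inferred cisplatin and oxaliplatin series. CCNE2 lies between 8.07 and 8.51 after cisplatin at IC90 and between 4.84 and 5.92 after oxaliplatin, and its controls spread from 6.74 to 8.45.

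Dose slopes over all 16 h arrays were called for 3507 genes with cisplatin (1623 rising, 1884 falling) and 1993 with oxaliplatin (1134 rising, 859 falling). Per 90 percent inhibition GDF15 rose by 2.89 ± 0.38 with cisplatin and 3.51 ± 0.40 with oxaliplatin, CEACAM1 by 2.69 ± 0.28 and 3.42 ± 0.30. LAMP3 rose by 2.55 ± 0.16 with cisplatin and RRAD by 3.86 ± 0.24 with oxaliplatin. PLK1 fell by 1.09 ± 0.09 and KIFC1 by 1.20 ± 0.17 with cisplatin, and CCNE2 fell by 2.47 ± 0.32, CCNA2 by 1.93 ± 0.16 and TOP2A, which encodes a topoisomerase, by 1.59 ± 0.25 with oxaliplatin. On treated arrays only, the slopes called were 866 and 1015.

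The slopes differed between the drugs for 2630 genes in the planned fit, but this count fell to 2 on treated arrays only, with an intercept per drug, and to 310 with the inferred run as a block. Of the 2630, 1580 had the other sign on treated arrays only. CCNE2 went from 3.36 ± 0.31 to 1.61, SPC25 from 1.97 ± 0.24 to 0.31, MYOF from -2.08 ± 0.31 to -0.63, and HMOX1 and AKR1C3 from -1.69 ± 0.26 and -1.69 ± 0.37 to 0.17 and 0.96. A difference in dose dependence was therefore not separated from an offset between the drugs' arrays.

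For some genes called above, other probe sets of the same gene were not called. After cisplatin at IC90 and 16 h these stood at -0.20 for FEZ1, -0.26 for TP53I11, 0.05 for XPC, 0.04 for JUNB, -0.06 for NR4A1, 0.14 for RPA1, 0.39 for CEACAM1 and -0.55 and 0.08 for MYC. After oxaliplatin they stood at -0.03 for FEZ1, -0.20 for TP53I11, 0.35 for XPC, -0.05 for SAT1, -0.31 for CDC6, 0.40 for RAD51C and -0.16 and -0.46 for SPC25. Between the drugs the 2 other SPC25 probe sets stood at 0.16 (adjusted p = 0.486) and 0.55 (adjusted p = 0.26), and another of TP53I11 at -0.06.

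Reference genes gave the scale of these changes. ACTB could not serve as one, since control number 1 at 16 h had 9.31 against 12.25 to 12.44 in the other 16 h controls. GAPDH was at 0.03 ± 0.08 after either drug at IC90 and 16 h, and its interval between the drugs was -0.16 to 0.15; another GAPDH probe set stood at -0.63 after cisplatin (adjusted p = 0.0797). SLC31A1, a copper transporter, was at 0.15 ± 0.25 and -0.31 ± 0.26, and MT2A, a metallothionein, at -0.10 ± 0.16 and 0.02 ± 0.16, none called. EGR1 was at 0.02 ± 0.16 after cisplatin and 0.48 ± 0.17 after oxaliplatin (adjusted p = 0.0594). The oxaliplatin value was called with the replicate block (adjusted p = 0.0196), the inferred run block (0.0145), array weights (0.0131), median centring (0.0358), the GAPDH covariate (0.0193) and brighter genes only (0.0469). It was also called without control number 4 (0.0302), oxaliplatin number 1 (0.0439) or oxaliplatin number 2 (0.0141). EGR1 therefore lies at the threshold and is not an unchanged reference. In the pooled fit at IC90 and 16 h, the integrated stress response, mismatch repair, NF-kappaB targets, histones and leukocyte markers were not called against control for either drug, and Fanconi and homologous recombination, apoptosis, cholesterol synthesis, the interferon response, epithelial markers and platinum transport were not called for cisplatin. The remaining lists were not called in that fit for either drug against control nor between the drugs: endothelial and fibroblast markers, heat shock, housekeeping, hypoxia and glycolysis, metallothioneins, NRF2 targets, ribosome biogenesis and the unfolded protein response. Within the inferred time course, heat shock, histones and ribosome biogenesis were called lower for cisplatin, and the integrated stress response and mismatch repair lower and NF-kappaB targets higher for oxaliplatin, only at the preset correlation (camera adjusted p = 0.0654, 0.514, 0.514, 0.157, 0.281 and 0.281 with an estimated correlation). Against the control of the oxaliplatin series, hypoxia and glycolysis was lower at IC10 and IC25 of oxaliplatin (medians -0.188 and -0.153, adjusted p = 0.000399 and 0.00144 with an estimated correlation), and the integrated stress response and cholesterol synthesis were lower at IC10 (medians -0.314 and -0.377, both adjusted p = 0.0165 with an estimated correlation). These comparisons use 1 control array, and hypoxia and glycolysis also differed by -0.141 between the controls of the cisplatin and oxaliplatin series (adjusted p = 0.0786 with an estimated correlation).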

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

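The tests of array run, RNA quality, dose strength and array background were chosen after the results were seen, as was the run block; the splits of the arrays and the test of the drug difference were chosen before.

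Cell-cycle genes were lower after oxaliplatin than after cisplatin at IC90 and 16 h, in a comparison that called 305 genes. Of 100 drawn splits of these 9 arrays (126 possible), 1, the real one, gave as many calls. The highest other gave 227 and mostly followed the inferred time-course run. Chance is thus unlikely but not excluded, a run structure is present, and with the run as a block the count was 90. In the 16 h IC90 arrays of the inferred time course, where both drugs were placed together, the median difference of G1/S and G2/M genes was 0.594 (0.307 to 0.878 over the 4 pairs of arrays). With the GAPDH covariate on all arrays it was 0.768, which argues against RNA quality as the whole cause. The value of 0.594 argues against run as the whole cause only as far as the inferred run holds. The way the clusters were cut tends to place both drugs in each, so this support is weak. At oxaliplatin IC25, both arrays had p53 target medians (1.016 and 1.218) below the 3 cisplatin IC90 arrays of the series (1.479 to 1.524). The G1/S median there differed from cisplatin IC90 by -0.575. At IC50 it differed by -0.869, and only 1 of 2 arrays had a lower p53 target median. A weaker p53 target response thus came with lower G1/S genes. Each drug was set against the controls of its own inferred run, 1 array for oxaliplatin and 2 for cisplatin. Drug, run and control thus differed together. The cisplatin p53 target median rose only from 1.299 at IC50 to 1.498 at IC90, so it gauges dose coarsely. A stronger oxaliplatin dose was therefore not excluded. A difference between the compounds may underlie the cell-cycle part, as a hypothesis found and tested on the same data.

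Of the 531 other genes called between the series arrays, 80.4 percent had the same sign in the time course. The half-width of the interval of this share was 3.4 percent, computed as if genes were independent. Genes are not independent replicates and were measured on the same arrays, so the real error may be larger. Their median there was 0.21 against 0.738, so drug and run cannot be told apart for their size. The bound set for this test was 80 percent. The requirement that the share exceed it by the half-width was added after the value was seen. With the error uncertain, the share does not decide the question. A run effect may contribute here.

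Between the drugs at 0 h 1612 genes were called. Oxaliplatin number 1 had a mean of 7.96 over 9 opposite-strand bacterial control probe sets, 6.85 SD above the other 50 arrays (5.14 to 6.75), and without it 0 genes were called. A high background in this array is a candidate explanation; the count was also 0 without cisplatin number 2, and 2973 and 3980 without cisplatin number 1 and oxaliplatin number 2. No biological explanation was tested.

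Below IC90 more genes were called after oxaliplatin than after cisplatin, by 5.75, 11, 8.51 and 5.55 times from IC10 to IC75. With the run as a block the ratios were 2.67, 1.72, 2.2 and 1.7. With the replicate number as a block the oxaliplatin counts stayed far above those of cisplatin at IC25, IC50 and IC75. The numbers were not read as pairs, so this block cannot decide the question. Deviations of control and oxaliplatin number 1 correlated at -0.39, -0.104, -0.639 and -0.443 from IC10 to IC75. For number 2 the values were 0.099, 0.007, 0.135 and 0.348. With array weights the order turned at 2 doses, with 2991 genes after cisplatin against 1785 after oxaliplatin at IC25 and 2533 against 121 at IC50, so the excess depends on the setting. The highest weight, 5.18, fell on cisplatin IC25 number 1, and the 2 cisplatin IC25 arrays were the most alike of all (correlation 0.9987). Whether this raised the weighted cisplatin count at IC25 was not tested. The run and the drug cannot be told apart here because these doses were placed in runs by drug. A run effect may account for part of the excess.

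For the other 16 h counts, 1 of 100 drawn splits gave as many as the 810 genes of cisplatin against control. The highest other gave 710, with cisplatin number 3 among the controls, and is the real split with 1 array moved. For oxaliplatin 1 of 35 splits gave as many as the 1062 genes (highest other 546), and no smaller share was possible. The split that reached each count was the real one, so chance is unlikely but not excluded. For the 16 h controls against arrays before treatment, 100 of 100 splits gave at least the 0 genes that limma called (477 at unadjusted p under 0.05; highest other 3). A real count of 0 fixes that outcome, so it says nothing about chance.

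The drugs also differed, by the test of the difference itself, in 45 genes at IC25, 34 at IC50 and 108 at IC75 (0, 0 and 1 with the run block), and in 2630 dose slopes, against 2 called in a fit of treated arrays only. Genes higher after cisplatin at IC90 and 16 h were CCNE2 (2.84), SPC25 (1.55), CDC6 (1.41), TTK (1.41), PRIM1 (1.38), PLK4 (1.35), RFC3 (1.34), DCK (1.32), FEN1 (1.29), KIF14 (1.18), BUB1B (1.17), CCNA2 (1.14), NDC80 (1.14), MCM6 (1.10), MCM4 (1.07), MCM3 (1.04), KIF2C (0.97), IMPA2 (0.94), AURKB (0.91), CCNB1 (0.82), HMMR (0.82), MCM2 (0.76), RPA1 (0.63) and RNF115 (0.36). Genes lower were MYOF (-1.75), KRT18 (-1.37), ACTG2 (-1.36), RRAD (-1.19), HMOX1 (-1.19), H2BC5 (-1.15), RGS5 (-1.09), PSMB9 (-1.05), CNN1 (-1.02), H2BC21 (-0.98), TYROBP (-0.93), PLAU (-0.85), MVP (-0.83), COL4A6 (-0.80), TP53I11 (-0.68), TAP1 (-0.67), ERCC1 (-0.64), FEZ1 (-0.58) and KRT8 (-0.57). Other probe sets of some of these genes were not called: SPC25 (0.16 and 0.55), RPA1 (0.60), RNF115 (-0.07), ERCC1 (-0.56 and -0.57), FEZ1 (-0.17) and TP53I11 (-0.06). With the inferred run as a block, 23 of these calls ended. Among the genes higher after cisplatin the log2 differences and adjusted p were then 0.59 and 0.647 for MCM4, 0.30 and 0.446 for RNF115, 0.84 and 0.371 for DCK, 0.69 and 0.241 for HMMR, 0.92 and 0.19 for KIF14, 0.89 and 0.162 for RFC3, 0.89 and 0.113 for NDC80, 1.10 and 0.1 for TTK, 0.57 and 0.0945 for CCNB1 and 0.58 and 0.0862 for RPA1. Among the lower ones they were -0.31 and 0.6 for TAP1, -0.31 and 0.561 for ERCC1, -0.32 and 0.403 for KRT8, -0.53 and 0.399 for COL4A6, -1.41 and 0.36 for MYOF, -0.57 and 0.351 for TYROBP, -1.29 and 0.334 for ACTG2, -0.51 and 0.282 for PLAU, -0.46 and 0.267 for PSMB9, -0.80 and 0.2 for KRT18, -0.53 and 0.17 for FEZ1, -0.59 and 0.163 for MVP and -0.81 and 0.069 for HMOX1. Some of these, such as ACTG2, FEZ1 and RPA1, kept nearly their size, so a lost call does not show that the run made the difference.

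Without single arrays 17 of these calls ended. Without oxaliplatin number 3 the adjusted p was 0.354 for KIF14, 0.216 for HMMR, 0.2 for FEZ1, 0.15 for MCM4, 0.131 for RNF115, 0.13 for DCK, 0.121 for MYOF, 0.114 for NDC80, 0.0998 for ACTG2, 0.086 for TYROBP, 0.0551 for ERCC1, 0.0537 for PLAU, 0.0533 for TTK and KRT8 and 0.0509 for RPA1. Without oxaliplatin number 4 it was 0.224 for FEZ1, 0.195 for KIF14, 0.108 for ACTG2, 0.104 for HMMR, 0.103 for MYOF, 0.0725 for MCM4, 0.0706 for NDC80, 0.0648 for RNF115, 0.0634 for TYROBP, 0.0629 for TAP1, 0.0581 for COL4A6 and 0.0532 for PLAU. Without oxaliplatin number 1 it was 0.117 for RNF115, 0.102 for MCM4, 0.097 for ACTG2, 0.0812 for MYOF and 0.075 for HMMR, and without number 2 it was 0.0588 for RNF115. Without cisplatin number 2 it was 0.15 for FEZ1, 0.134 for KIF14, 0.109 for RNF115, 0.0899 for HMMR, 0.0862 for ACTG2 and 0.0601 for MYOF, and without number 5 0.171 for RNF115, 0.0966 for ACTG2, 0.0867 for KIF14, 0.0676 for MCM4 and 0.0592 for HMMR. Without cisplatin number 1 it was 0.0909 for FEZ1, 0.0833 for KIF14 and 0.0521 for ACTG2. Without number 3 it was 0.0946 for MCM4, 0.0595 for FEZ1 and 0.055 for ACTG2, and without number 4 0.0898 for MCM4, 0.0611 for ACTG2 and 0.0559 for RNF115.

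Single arrays stood apart from their group by Dixon's test in 20 of 354 tests at 16 h, on 10 arrays; chance gives about 1 in 20. In cisplatin number 2 these were TNFSF9 (9.59), ATF3 (4.72), HMMR (9.04) and the opposite-strand control probe sets (5.14). In oxaliplatin number 2 they were MCM2 (10.5), AURKB (11.36), RCC1 (8.97) and MYOF (6.37). Others were RGS5 in cisplatin number 1 (4.43) and oxaliplatin number 1 (6.5), PDC in cisplatin number 3 (4.23), IFIT1 in cisplatin number 5 (10.2), SLC30A1 in oxaliplatin number 3 (9.4) and control number 4 (8.23), DDB2 (9.35) and DHRS2 (8.78) in control number 4, MCM2 (11.16) and KIF2C (9.11) in control number 2, and IMPA2 (9.05) and ACTB (9.31) in control number 1.

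Among 1615 probe sets that match several genes or none, 93 were called after cisplatin (68 higher, 25 lower) and 132 after oxaliplatin (83 higher, 49 lower) at IC90 and 16 h.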

How the results depend on the processing

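The inferred run block, the GAPDH covariate, the fits without the 2 arrays that stood apart, treated-only slopes and crossed pairing were chosen after the results were seen; the other settings were planned before. IC10 to IC75 stand for the 16 h comparisons with control, and a drug difference is cisplatin against oxaliplatin; values are genes called, or lists where named. Each value below differs by over 1.5 times from the one in the report. Counting all probe sets gave 4 for cisplatin IC90 2 h, 0 for oxaliplatin IC90 0 h, 26 for cisplatin IC25, 2499 for the drug difference at IC90 0 h, 52 for the drug difference at IC50 and 5298 for cisplatin slope. Brighter genes only gave 0 for cisplatin IC90 2 h, 0 for oxaliplatin IC90 0 h, 2 for oxaliplatin IC90 6 h, 396 for the drug difference at IC90 0 h, 2 for the drug difference at IC90 2 h, 19 for the drug difference at IC50, 8 for lists of oxaliplatin IC90 16 h, 6 for lists of the drug difference at IC90 16 h and 1952 for cisplatin slope. It also gave 1579 for the slope difference. Trend and robust eBayes gave 2 for cisplatin IC90 2 h, 1 for oxaliplatin IC90 2 h and 1 for the drug difference at IC90 2 h. Array weights, which ran from 0.188 to 5.18, gave 35 for cisplatin IC90 2 h, 25 for cisplatin IC90 6 h, 0 for oxaliplatin IC90 0 h, 38 for oxaliplatin IC90 6 h, 3026 for cisplatin IC90 16 h, 2334 for oxaliplatin IC90 16 h, 1262 for cisplatin IC90 24 h, 1488 for oxaliplatin IC90 24 h and 54 for cisplatin IC10. They also gave 2991 for cisplatin IC25, 2533 for cisplatin IC50, 1659 for cisplatin IC75, 595 for oxaliplatin IC10, 1785 for oxaliplatin IC25, 121 for oxaliplatin IC50, 2240 for oxaliplatin IC75, 0 for the drug difference at IC90 0 h and 2 for the drug difference at IC90 6 h. They also gave 749 for the drug difference at IC90 16 h, 26 for the drug difference at IC90 24 h, 1552 for the drug difference at IC10, 3899 for the drug difference at IC25, 6 for the drug difference at IC50, 1026 for the drug difference at IC75, 172 for control 16 h against before treatment and 1449 for genes called in the same direction by both drugs. Quantile normalization gave 2 for cisplatin IC90 2 h, 0 for oxaliplatin IC90 0 h, 1 for oxaliplatin IC90 2 h, 2 for the drug difference at IC90 24 h and 3 for the drug difference at IC10. Median centring gave 1 for the drug difference at IC90 2 h. The replicate block gave 34 for cisplatin IC25, 105 for cisplatin IC50, 221 for cisplatin IC75, 620 for oxaliplatin IC10, 882 for oxaliplatin IC25, 847 for oxaliplatin IC50, 1242 for oxaliplatin IC75, 1 for the drug difference at IC90 6 h and 13 for the drug difference at IC10. It also gave 207 for the drug difference at IC25, 84 for the drug difference at IC50 and 217 for the drug difference at IC75. Crossed pairing gave 6 for the drug difference at IC10. Only the 2 groups compared gave 668 for oxaliplatin IC90 16 h, 2 for cisplatin IC10, 11 for cisplatin IC25, 68 for cisplatin IC75, 14 for oxaliplatin IC10 and 144 for oxaliplatin IC50. Pooled untreated arrays as the control gave 10 for cisplatin IC90 2 h, 40 for cisplatin IC90 6 h, 2508 for oxaliplatin IC90 0 h, 54 for oxaliplatin IC90 2 h and 56 for oxaliplatin IC90 6 h. Arrays before treatment as the control gave 7 for cisplatin IC90 2 h, 24 for cisplatin IC90 6 h, 1652 for oxaliplatin IC90 0 h, 34 for oxaliplatin IC90 2 h and 53 for oxaliplatin IC90 6 h. Camera with an estimated correlation gave 1 for lists of cisplatin IC90 16 h, 5 for lists of oxaliplatin IC90 16 h and 3 for lists of the drug difference at IC90 16 h. Splitting the controls between the drugs gave a median of 232.5 for genes called in the same direction by both drugs. The inferred run block gave 2 for cisplatin IC90 6 h, 129 for oxaliplatin IC90 0 h, 4 for oxaliplatin IC90 6 h, 69 for cisplatin IC50, 8 for oxaliplatin IC10, 31 for oxaliplatin IC25, 152 for oxaliplatin IC50, 297 for oxaliplatin IC75 and 2 for the drug difference at IC90 2 h. It also gave 1 for the drug difference at IC90 6 h, 90 for the drug difference at IC90 16 h, 0 for the drug difference at IC25, 0 for the drug difference at IC50, 1 for the drug difference at IC75 and 310 for the slope difference. The GAPDH covariate gave 2 for cisplatin IC90 6 h, 0 for oxaliplatin IC90 0 h, 3 for oxaliplatin IC90 6 h, 330 for cisplatin IC90 24 h, 141 for the drug difference at IC25 and 65 for the drug difference at IC50. Without the 2 arrays that stood apart the values were 0 for oxaliplatin IC90 0 h, 6 for oxaliplatin IC90 6 h, 1224 for cisplatin IC90 16 h, 349 for cisplatin IC90 24 h, 37 for oxaliplatin IC10, 0 for the drug difference at IC90 0 h, 137 for the drug difference at IC25 and 64 for the drug difference at IC50. Slopes on treated arrays only gave 866 for cisplatin slope, 1015 for oxaliplatin slope and 2 for the slope difference. The cause of these shifts was not tested, except that in the run block the IC10 to IC75 groups were placed in runs by drug. These runs are linked only by the controls and the IC90 arrays. Leaving out 1 replicate at a time gave 0 to 5 for cisplatin IC10, 5 to 13 for cisplatin IC25, 18 to 54 for cisplatin IC50, 41 to 128 for cisplatin IC75, 517 to 1353 for cisplatin IC90 16 h, 1 to 2 for cisplatin IC90 2 h and 0 to 1 for the drug difference at IC25. The ranges were further 5 to 24 for the drug difference at IC50, 5 to 17 for the drug difference at IC75, 0 to 3980 for the drug difference at IC90 0 h, 113 to 442 for the drug difference at IC90 16 h, 0 to 271 for the drug difference at IC90 2 h, 0 to 1 for the drug difference at IC90 6 h and 0 to 3 for control 16 h against before treatment. The ranges were further 7 to 149 for oxaliplatin IC10, 35 to 443 for oxaliplatin IC25, 137 to 696 for oxaliplatin IC50, 266 to 876 for oxaliplatin IC75, 0 to 3551 for oxaliplatin IC90 0 h and 0 to 150 for oxaliplatin IC90 2 h. Leaving a pair with 1 array lowers its precision, and the lone array is then assumed to vary like the other groups. Of 5759 values for named genes under all settings, 4387 planned and 902 added ones kept their direction and side of the threshold, 193 and 53 lost the call, 153 and 69 gained one, and 2 turned sign, both in the slope difference on treated arrays only: HMOX1 to 0.17 and AKR1C3 to 0.96. For slopes these cover only genes named with a slope, a choice made after the treated-only result was seen; among 116 genes examined for the text, 27 of 74 called slope differences turned sign on treated arrays only, and 1 of 68 cisplatin and 2 of 96 oxaliplatin slopes. The log2 micromolar dose scale moved none of the 3 slope counts by over 1.5 times. Of 638 counts under all settings, those within 1.5 times their value in the report lay above it in 96, below in 191 and at it in 107 under the settings chosen before, and in 37, 7 and 32 under the added ones. All settings chosen before were run.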

Other observations

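The test of gene length was written before its result was seen; the other values here were looked at after the data were examined.

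Platinum lesions block transcription, so long genes might fall more than short ones, a hypothesis set before the test. The Spearman correlation of gene span with log2 change had a median of -0.079 over 12 treated time-course arrays (-0.222 to 0.125) and 0.037 over 9 untreated ones (-0.141 to 0.141). The ranges overlap, so the test did not decide.

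The actin 3' probe set was low in arrays where its opposite-strand partner was high, as in the 6 h control (9.61 and 12.1). The actin 3' to 5' difference was therefore not used as a measure of RNA quality. In the control-labelled arrays of the inferred time course the opposite-strand value lay between 11.23 (0 h) and 12.1 (6 h). It was as high in some cisplatin arrays, such as 2 h number 2 (12.02), and reached at most 10.01 in oxaliplatin arrays (0 h number 2). The early control and oxaliplatin arrays thus differed in this probe set, and the cause was not tested. The GAPDH 3' minus 5' value averaged 0.37 in 16 h controls, 0.844 after cisplatin IC90 and 0.653 after oxaliplatin IC90.

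The highest correlation between 2 arrays was 0.9987, between the cisplatin IC25 arrays.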
